A study of Mus musculus with 31 samples.

How the data were processed

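The series holds 31 samples of mouse fibroblasts: 17 of ATAC-seq, 8 of BRG1 ChIP-seq with input, and 6 of RNA-seq. RNA-seq was run on female dermal fibroblasts of a CAST/Ei and 129/Sv/Jae hybrid in 3 groups of 2 libraries: WT, Xist-deleted line 1 and Xist-deleted line 2. Per the protocol, total RNA was depleted of ribosomal RNA and sequenced as 50 bp pairs with a directional kit. BRG1 ChIP was native, with benzonase digestion. Per-sample tracks of ATAC-seq and ChIP-seq, samples treated with siRNA and ATAC-seq of line 2 were not analysed here.

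Exon values per RefSeq transcript are expected counts that the authors made with HOMER, per the file headers without normalization and in steps of 0.5. Allele values of X-linked genes are expected counts per parental allele, as deposited, with a lowest value of 0.5 that stands for 0, and the authors' mus fraction is the mus reads over all allele reads of a library. The authors also deposited a class per gene and lists of X-linked sites classed Monoallelic, Biallelic or XiRestored for accessibility and for BRG1, as coordinates with no score. The labels tie the accessibility lists to WT and line 1 dermal fibroblasts and WT embryonic fibroblasts, and the BRG1 lists to WT and line 1. The submitters' processing notes name Trim Galore 0.4.1, TopHat2, SAMtools 0.1.18, bedtools 2.25.0, HOMER, Bowtie2 2.2.7, MACS2, edgeR, Novoalign 3.00.02 and the mm10 build. Which tool did which step, whether counting used the strand, and how classes were called are not given in the sources used here.

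The design assumed counts, and the unit turned out to be expected counts. Exon values were therefore rounded to whole numbers, with 0.5 rounded up, and allele values with 0.5 rounded down. Of 28972 transcripts, 4502 were dropped because 3356 symbols had several, of which the transcript with the highest total was used, giving 24470 symbols. After filterByExpr 12910 were tested, 415 on the X with Xist and 12495 on autosomes. Totals in the header were 11 M and 16.4 M for WT, 10.5 M and 20.1 M for line 1, and 11.6 M and 18.7 M for line 2, and counts used were 4.06 M, 6.21 M, 3.81 M, 7.06 M, 4.19 M and 6.96 M in the same order (M, 1e+06 counts). The first library of each group was the shallower, so replicate number also stands for depth. Differences between replicates 1 and 2 correlated across genes between groups (Pearson 0.54, 0.59 and 0.53), so numbers share a batch or depth effect, and values with replicate number as a block are given beside the others. The common biological coefficient of variation was 0.17, and Pearson's r of log2 CPM between replicates was 0.983 in WT, 0.964 in line 1 and 0.985 in line 2.

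All 6 libraries entered 1 quasi-likelihood fit in edgeR 4.0.16 (R 4.3.3) with a mean per group, TMM scaling and 3 residual degrees of freedom. Contrasts were each line against WT, the mean of both lines against WT, and line 2 minus line 1, with Benjamini-Hochberg adjusted p under 0.05. Gene groups were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01 and again with the correlation estimated. The 19 gene lists held 450 genes, of which 356 were tested: X escape, X-inactivation centre, SWI/SNF, other remodelers, Polycomb, inactive X maintenance and Xist partners, replication and mitosis, p53 targets, interferon-stimulated, matrix and fibroblast, contractile, keratinocyte, leukocyte, endothelial, adipocyte, melanocyte and Schwann, Hox, imprinted, and inflammatory genes. Chromosome medians have 95% bootstrap intervals over genes. Site classes were compared by overlap of at least 1 base and by distance to transcription starts (1 kb), with Fisher's exact test across sites. RNA near sites used X-linked genes with a start within 10 kb of a site and sets of at least 5 genes.

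These tests, the lists, the alternatives for them and the rule for naming genes were fixed before the data were examined. Xist came first. For each line, named genes were the 8 with the highest and the 8 with the lowest log2 fold change. They had an adjusted p under 0.05, a mean log2 CPM of at least 3 and both libraries of the line beyond both WT libraries. Predicted genes, microRNA, small nucleolar and ribosomal symbols were left out. For both lines together 8 were taken each way by the smaller absolute change, between the lines 5, on the X 6 by the mean of both lines, and up to 4 per list by adjusted p. Genes nearest to up to 6 sites in both XiRestored classes completed the rule; 1 gene that it took is not reported here. Allele tests, tests of mus share near sites, tests of shared controls, alternatives for the genes shared by both lines, leave-one-out tests of lists and unrounded, thinned and densest-gene alternatives were chosen after the data were seen.

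Genes with 0 counts in a group are given as a bound against a floor of 3 counts over the group. Genes with more than 0 and up to 3 counts are given as a ratio with a 95% counting interval, which covers counting error only. Some totals were 0.5 counts, which the ratio used unchanged and the interval rounded up. Such a ratio can exceed a bound from 0 counts without a larger change. The allele test was an edgeR interaction of allele and group over 205 genes. Mus share near sites, by distance to the gene body, was tested with 1e+05 permutations of genes. Alternatives included DESeq2 1.42.0 Wald tests and size factors, TMM from autosomal genes, no filter, a filter of CPM of at least 1 in 4 libraries, replicate number as a block, a fold threshold, the 2 compared groups alone, and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

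The gene test was tested on simulated data with 50 changed genes per fold size among 12910. At 1.5, 2, 4 and 8-fold it recovered 2, 14, 45 and 49 for line 1, 1, 24, 40 and 46 for line 2, 8, 29, 46 and 48 for the mean, and 1, 19, 41 and 46 between lines. False calls were 16 of 126 for line 1, 12 of 123 for line 2, 4 of 135 for the mean and 7 of 114 between lines, so the share was above the nominal 5% in all but the mean. A shift of 0.2 in X-linked genes and of 1 in interferon-stimulated genes passed camera in both lines, and unchanged Hox genes did not pass. Simulated genes varied independently of each other and without a replicate effect, so sensitivity in the real data may be lower. The allele test recovered 7 of 20 genes at 4-fold and 18 of 20 at 16-fold, with 0 false calls among the unchanged genes of the 205. Its simulated reads varied by counting alone, without spread between libraries, so false calls in the real data may be more frequent.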

Results

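Xist is the long noncoding RNA that coats and silences the inactive X chromosome of female cells. RNA was compared between wild-type (WT) female mouse dermal fibroblasts and cells of 2 lines in which Xist had been deleted from the inactive X, called line 1 and line 2 here. All 3 groups came from a hybrid of CAST/Ei and 129/Sv/Jae mice, so reads over differing bases could be assigned to either parental X, and each group had 2 RNA libraries (n = 2). Chromatin accessibility (ATAC-seq) and binding of BRG1, the ATPase of the SWI/SNF remodeler, were reported through the authors' lists of classified sites on the X.

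Xist RNA was close to absent in both lines. The gene, at X:103460374-103483233 on mm10, had 531 ± 144 CPM (library-scaled read counts; SD, n = 2) in WT, 0.61 ± 0.476 in line 1 and 0.626 ± 0.486 in line 2. The log2 fold change was -9.85 (SE 0.47, adjusted p = 0.000276) in line 1 and -9.88 (SE 0.46, adjusted p = 0.00179) in line 2. Tsix, the antisense transcript that overlaps Xist, fell with it, from 41.9 ± 14.3 CPM in WT to a log2 ratio of -8.77 (95% counting interval -14.08 to -6.29) in line 1 and -8.21 (-10.85 to -5.94) in line 2. Whether the counting of exons used the strand is not given in the sources used here, so reads of Xist and Tsix may be mixed. Smarca4, which encodes BRG1, had 549 ± 72.2 CPM in WT, 472 ± 75.8 in line 1 and 512 ± 66.3 in line 2. Within replicate numbers Smarca4 was lower in both lines, at 600 and 498 CPM in WT, 526 and 418 in line 1 and 559 and 465 in line 2, and was not called (log2 fold change -0.22, adjusted p = 0.526, and -0.10, adjusted p = 0.914).

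Line 1 differed from WT at genes of innate immunity and positional identity, among others. Among the genes that rose most, of those with a mean log2 CPM of at least 3, were Pde3b, a phosphodiesterase (log2 fold change 6.58, SE 0.19), Adamtsl3, a secreted matrix protein (6.35, SE 0.37), Pcdh1, a protocadherin (6.19, SE 0.45), Lrrc15, a marker of activated fibroblasts (6.10, SE 0.50), and Sema7a, a membrane-anchored semaphorin (6.08, SE 0.42). Gbp3 (6.14, SE 1.30), Ddx60 (6.11, SE 0.77) and Oasl2 (6.09, SE 1.05), which interferon induces, rose as well. Ptprz1, a receptor phosphatase, and Hoxc10, a positional homeobox gene, had 0 counts in both line 1 libraries and were at least 446-fold and at least 258-fold lower than in WT, against a floor of 3 counts over the group. Near-complete loss was also seen for Hoxc9 (log2 ratio -11.18, counting interval -15.48 to -7.69), Hoxc8 (-10.80, -15.10 to -7.32), Slc5a7, the choline transporter (-10.63, -15.93 to -8.15), the imprinted Peg3 (-10.12, -14.43 to -6.64), Hoxc6 (-9.20, -12.25 to -7.34) and Ptgis, prostacyclin synthase (-9.10, -11.74 to -6.83). Hoxc9, Hoxc8 and Peg3 each rested on 0.5 counts over the line 1 libraries, so their ratios cannot be ranked against the bounds. In all, 1846 of 12910 genes tested by edgeR changed, 871 higher and 975 lower, and 1389 of them by at least 2-fold. The count was 775 without WT replicate 1 and 718 without WT replicate 2, and 21 and 19 of 74 calls on named genes were lost without these libraries. It was 4182 with replicate number as a block and 1257 with the 2 compared groups alone.

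Genes induced by interferon were the most uniformly raised group of line 1. Of 28 measured interferon-stimulated genes 23 rose, 27 when adjusted over the list alone, with a median log2 fold change of 4.18 (camera adjusted p = 2.63e-14, but adjusted p = 0.37 with an estimated correlation). Examples were Rtp4 (4.94), the deubiquitinase-like Usp18 (5.57), the antiviral Ifit1 (4.97) and Oas1a (log2 ratio 7.51, counting interval 5.65 to 10.57). The list's median level was 7.57 and 6.08 log2 CPM in the line 1 libraries against 3.20 and 2.69 in WT, so the first library of each group was the higher. Inflammatory cytokines and chemokines rose in part, with 6 of 16 higher and 1 lower, 9 and 1 when adjusted over the list alone, and a median of 1.08 (adjusted p = 0.000102, adjusted p = 0.24 with an estimated correlation). Il33, an alarmin, had a log2 ratio of 8.53 (counting interval 6.98 to 10.81), its receptor Il1rl1 rose by 2.71, Cxcl1 rose by 3.72 and Cxcl12 fell by 1.01.

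Genes of positional identity, imprinting and contraction were lower in line 1. Of 28 measured Hox genes 14 fell and 2 rose, 17 and 2 when adjusted over the list alone, with a median of -1.85, unchanged with 3 members set to their bound (adjusted p = 1.41e-07, adjusted p = 0.24 with an estimated correlation). Besides the Hoxc genes, Hoxb9 fell by 3.03. Of 23 imprinted genes 11 fell and 1 rose, 12 and 2 when adjusted over the list alone, with a median of -0.72 (adjusted p = 8.31e-07, adjusted p = 0.22 with an estimated correlation). The maternally expressed noncoding RNAs Meg3 (log2 ratio -11.02, -15.33 to -7.54) and Rian (-9.22, -14.53 to -6.74) and the paternally expressed Dlk1 (-4.53) and Nnat (-3.15) were among them, and without line 1 replicate 2 the median of imprinted genes was -1.13. Of 14 contractile and smooth muscle genes 8 fell, 10 when adjusted over the list alone, with a median of -1.36 (adjusted p = 3.06e-07, adjusted p = 0.22 with an estimated correlation). Calponin Cnn1 fell by 5.18, leiomodin Lmod1 by 4.78, the light chain Myl9 by 2.23 and smooth muscle actin Acta2 by 1.25. Of 5 measured keratinocyte and epithelial genes 3 fell, 4 when adjusted over the list alone, with a median of -3.03 (adjusted p = 0.00855, adjusted p = 0.24 with an estimated correlation). These were desmoplakin Dsp (-5.58), Krt19 (log2 ratio -7.29, -9.58 to -5.74) and Trp63 (-3.03).

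**Figure D1:**
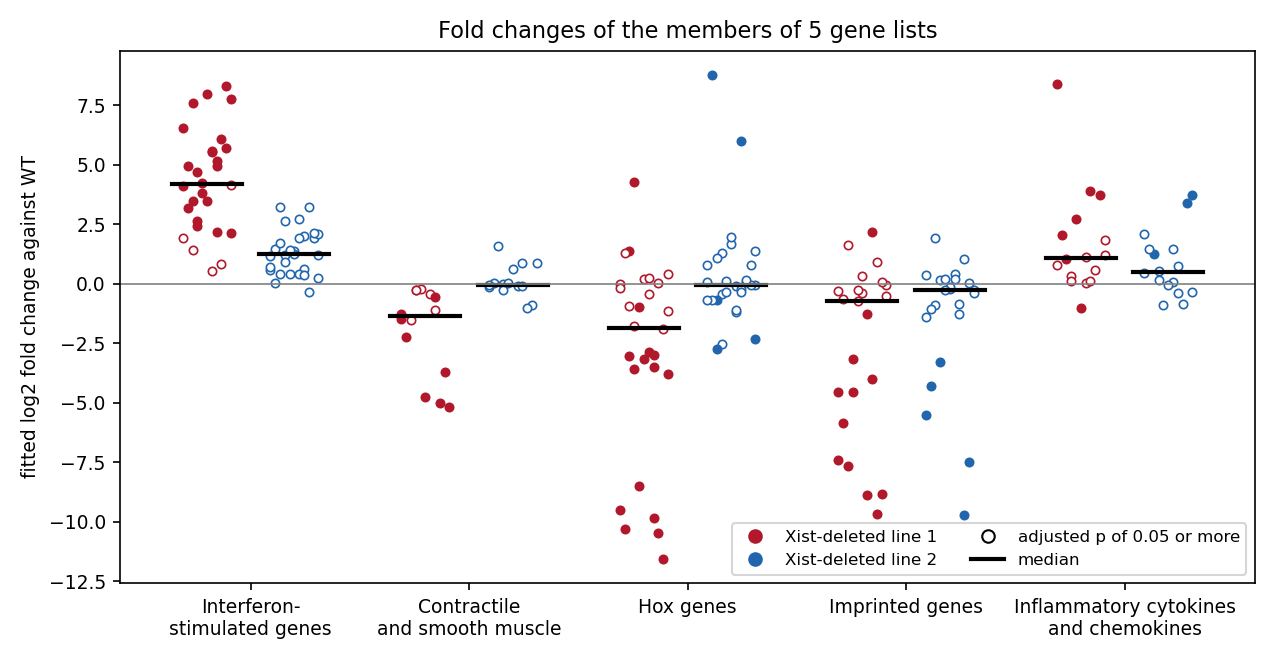
Each point is the fitted log2 fold change of a list member against WT in line 1 (red) or line 2 (blue), filled where the adjusted p was under 0.05, with black bars at the list medians. Interferon-stimulated genes had a median of 4.18 in line 1 and 1.24 in line 2, and Hox genes -1.85 and -0.05.

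The remaining lists did not pass as groups in line 1. Extracellular matrix and fibroblast genes went both ways, 6 of 38 higher and 1 lower (6 and 2 when adjusted over the list alone; median -0.10, adjusted p = 0.98). The proteases Mmp3 (6.74), Mmp13 (log2 ratio 7.20, counting interval 3.69 to 11.53) and Mmp2 (2.36) rose, and the protease inhibitor Timp3 fell by 7.66. SWI/SNF subunits had a median of -0.20 (adjusted p = 0.169), and 2 of 25, Smarcd3 (-0.93) and Dpf1 (-1.22), fell, also when adjusted over the list alone. Of 26 other chromatin remodelers Chd7 (3.39) and Ino80 (0.56) rose and Chd9 (-0.68) fell, the same numbers as when adjusted over the list alone (median -0.05, adjusted p = 0.814). Of 32 Polycomb subunits Phf19 (0.80) rose and Rybp (-1.33), Epop (-1.17) and Bcor (-0.53) fell, again 1 and 3 when adjusted over the list alone (median -0.03, adjusted p = 0.814). Among 33 genes of inactive X maintenance and Xist partners, H2afy2, which encodes the histone variant macroH2A2, fell by 4.03 and was the 1 call, also when adjusted over the list alone (median -0.01, adjusted p = 0.989). DNA replication and mitosis genes gave 0 calls of 30 by edgeR, 0 by DESeq2, 0 when adjusted over the list alone, 6 with the replicate block and 3 at an unadjusted p under 0.05 (median 0.11, adjusted p = 0.363). Of 19 p53 targets Tnfrsf10b (0.51) rose and Gdf15 (-2.70) fell, 0 and 1 when adjusted over the list alone (median 0.09, adjusted p = 0.982). With the replicate block more members were called: 16 matrix genes, 7 SWI/SNF subunits, 9 other remodelers, 10 Polycomb subunits, 6 genes of inactive X maintenance and 5 p53 targets, against 8, 2, 4, 4, 2 and 0 by DESeq2. These small medians moved with single libraries, several in sign. Without WT replicate 1 the median of SWI/SNF subunits was -0.09 and without line 1 replicate 2 it was -0.06. Without line 1 replicate 1 and without line 1 replicate 2 it was -0.37 and 0.09 for matrix genes, -0.21 and 0.39 for p53 targets, -0.17 and 0.05 for other remodelers and -0.13 and 0.09 for Polycomb subunits.

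Markers of other cell types were mostly too low to test, and moved apart in line 1. Of 4 measured macrophage and leukocyte genes Cd14 (2.18) rose and Lyz2 (-1.91) fell, 2 and 1 when adjusted over the list alone (median 0.38, adjusted p = 0.814). Of 6 endothelial genes 2 fell, also when adjusted over the list alone: Kdr, a VEGF receptor, was at least 24.1-fold lower, and Erg had a log2 ratio of -4.55 (-7.26 to -2.19; list median -0.74, adjusted p = 0.1, and 0.0145 without WT replicate 2). All 3 adipocyte genes passed when adjusted over the list alone, lower, and 0 over all genes tested by edgeR, against 3 at an unadjusted p under 0.05, 2 by DESeq2 and 3 with the replicate block (median -1.49, adjusted p = 0.1). Of 4 melanocyte and Schwann genes Mitf (2.39) rose and Ngfr (log2 ratio -4.11, -7.22 to -2.14) fell, 1 and 1 when adjusted over the list alone (median -0.25, adjusted p = 0.989). The leukocyte median was 1.19 without WT replicate 1 and 1.14 without line 1 replicate 1. The endothelial median was -0.38 without WT replicate 1, and that of melanocyte and Schwann genes lay between -0.54 without line 1 replicate 1 and 0.08 without line 1 replicate 2.

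Line 2 differed from WT at fewer genes. Of genes with a mean log2 CPM of at least 3, Adamtsl3 rose most (log2 fold change 8.95, SE 0.34, adjusted p = 0.00166), followed by Pcdh1 (6.30, SE 0.45), Pde3b (4.50, SE 0.20), the complement protease Masp1 (4.44, SE 0.36), the cytochrome Cyp2j6 (4.19, SE 0.29), the Wnt antagonist Sfrp2 (3.98, SE 0.51), Clec14a (3.95, SE 0.29) and Apol9a (3.75, SE 0.45). Of the same genes the Wnt antagonist Dkk2 fell most (-6.54), followed by the glycoprotein Gpnmb (-5.40), Tspan11 (-5.35), the receptor Gpr149 (-4.88), the protocadherin Dchs1 (-4.73), Lgr6 (-4.45), the amino acid transporter Slc38a4 (-4.28) and the pericyte proteoglycan Cspg4 (-3.91). In all, 462 of 12910 genes changed by edgeR, 223 higher and 239 lower, and 408 of them by at least 2-fold. This count rested on every library: it was 52 without WT replicate 1, 28 without WT replicate 2, 46 without line 2 replicate 1 and 23 without line 2 replicate 2, and 16, 20, 18 and 25 of 37 calls on named genes were lost. It was 1568 with the replicate block. With the 2 compared groups alone it was 790, against 1257 in line 1, so the gap between the lines was smaller without the shared fit.

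Imprinted and inflammatory genes moved as groups in line 2, and interferon-stimulated genes did so without single calls by edgeR. Of 23 imprinted genes 5 fell and 0 rose, 8 and 3 when adjusted over the list alone, with a median of -0.28 (adjusted p = 0.00203, adjusted p = 0.67 with an estimated correlation). Meg3 (log2 ratio -11.05, -15.35 to -7.57), Rian (-7.92, -9.94 to -6.11), Nnat (-3.28) and Slc38a4 (-4.28) were among them, and the median of imprinted genes was -0.17 without WT replicate 1. Interferon-stimulated genes had a median of 1.24 (adjusted p = 0.000141, adjusted p = 0.90 with an estimated correlation) with 0 of 28 called by edgeR, also when adjusted over the list alone, against 10 at an unadjusted p under 0.05, 8 by DESeq2 and 10 with the replicate block. Their median was 0.50 without line 2 replicate 1 and 1.68 without line 2 replicate 2, so it depended on single libraries. Replicate 1 was the higher in WT as well, with list medians of 3.20 and 2.69 log2 CPM. Those of line 2 were 5.01 and 3.68, above WT within each replicate number. Rtp4 stood at 1.99 (adjusted p = 0.124) and Isg15 at 2.63 (adjusted p = 0.222). Of 16 inflammatory genes Ccl9 (3.74), Cxcl1 (3.40) and Cx3cl1 (1.25) rose, 6 when adjusted over the list alone, with a median of 0.50 (adjusted p = 0.0151, adjusted p = 0.67 with an estimated correlation, and 0.0555 with the replicate block). Without WT replicate 2 the inflammatory median was 0.18.

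Hox genes moved apart in line 2. Hoxa9 (log2 ratio 10.07, counting interval 6.58 to 14.37) and Hoxa10 (6.00), nearly silent in WT, rose, and Hoxd4 (-2.33), Hoxd9 (-2.76) and Hoxb9 (-0.67) fell, 6 and 7 of 28 when adjusted over the list alone, with a median of -0.05 (adjusted p = 0.81). Of 38 matrix and fibroblast genes the protease Fap (2.74) alone rose, also when adjusted over the list alone (median 0.01, adjusted p = 0.763). Of 5 keratinocyte genes Dsp fell by 3.85, again the 1 call over the list alone (median -0.66, and -1.14 without line 2 replicate 2; adjusted p = 0.18). Of 6 endothelial genes Kdr (-2.96) and Erg (at least 11.9-fold lower) fell, 3 and 1 higher when adjusted over the list alone (median -0.49, adjusted p = 0.19, and 0.0249 without WT replicate 2; the median was 0.28 without WT replicate 1 and -0.16 without line 2 replicate 1). Melanocyte and Schwann genes had a median of -0.43 (adjusted p = 0.0676), which passed without WT replicate 2 (0.00534) or line 2 replicate 1 (0.0037, median -1.16), with 0 of 4 called by edgeR, 1 when adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 by DESeq2 and 1 with the block.

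Lists of chromatin regulators and growth gave no calls in line 2 by edgeR or DESeq2, over all genes or adjusted over the list alone. Calls numbered 0 of 25 SWI/SNF subunits (median -0.06, adjusted p = 0.374; 1 at an unadjusted p under 0.05), 0 of 26 other remodelers (-0.04, 0.712; 3), 0 of 32 Polycomb subunits (-0.02, 0.763; 3) and 0 of 33 genes of inactive X maintenance (-0.06, 0.578; 1). They numbered 0 of 30 replication genes (-0.02, 0.763; 0), 0 of 19 p53 targets (-0.05, 0.778; 2), 0 of 14 contractile genes (-0.04, 0.81; 3), 0 of 4 leukocyte genes (0.33, 0.763; 2) and 0 of 3 adipocyte genes (-0.38, 0.763; 0), each value in the same order. With the replicate block, 2 inactive X maintenance genes, 1 SWI/SNF subunit, 3 remodelers, 2 p53 targets, 3 contractile genes and 1 leukocyte gene were called. Medians this small moved with single libraries: without line 2 replicate 1 they were -0.14 for other remodelers, -0.12 for inactive X maintenance, -0.14 for contractile, 0.58 for leukocyte and 0.06 for adipocyte genes.

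A common set of genes moved the same way in both lines, with 95 higher and 145 lower in each. Besides Adamtsl3, Pcdh1, Pde3b, Clec14a, Apol9a, Cyp2j6 and Masp1, the lactate exporter Slc16a3 rose in both (4.21 in line 1, 3.68 in line 2). Lower in both were Slc38a4 (-5.86 and -4.28), Nnat (-3.15 and -3.28), P-cadherin Cdh3 (-7.96 in line 1; adjusted p = 0.00424 in line 2), Dkk2 (-2.80 and -6.54), Hapln4, a link protein (-2.74 and -3.54), Lgr6 (-2.33 and -4.45), Lrrc8d, a subunit of volume-regulated anion channels (-2.09 and -2.13), and Khdrbs3, an RNA-binding protein (-2.85 and -2.08). Another 51 genes were called in opposite directions. Independent lists of these sizes would share 15 higher and 18 lower and oppose at 33, and 20 simulations of unchanged genes with the shared WT libraries gave means of 0, 0 and 0.05. The simulations held no changed gene in either line, so they could give hardly any shared calls and do not bear on their source. A difference of the WT cells themselves would also appear in both lines, and was not tested. In the mean of both lines 966 genes changed by edgeR, 347 higher and 619 lower (2878 with the replicate block).

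Because both lines were compared with the same 2 WT libraries, part of the likeness of their fold changes is built in. Pearson's r across genes, which are not independent replicates, was 0.37 between the lines, below the mean of 0.51 in the simulations, while the covariance was 0.40 against 0.0694. Shared calls depended on single libraries: without WT replicate 1 there were 9 higher and 20 lower, without WT replicate 2 there were 4 and 11, without line 2 replicate 1 there were 13 and 15, and without line 2 replicate 2 there were 7 and 5. Without line 1 replicate 1 there were 135 and 238, and without line 1 replicate 2 there were 148 and 186. The mean of both lines gave 282 genes without WT replicate 1, 267 without WT replicate 2, 1558 without line 1 replicate 1, 500 without line 2 replicate 1 and 394 without line 2 replicate 2.

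The 2 lines, which carry the same deletion by the labels, differed from each other at almost as many genes as line 1 from WT. In line 2 minus line 1, Ptprz1 was at least 260-fold and Hoxc10 at least 248-fold higher, with Hoxc9 (log2 ratio 10.81, counting interval 7.33 to 15.12), Peg3 (10.32, 6.84 to 14.63) and the transcription factor Ebf3 (9.72, 7.45 to 12.36) also higher. Igfbp5, an insulin-like growth factor binding protein (-8.46), Tspan11 (-8.22), Gpr149 (-7.36), Arhgap22 (-5.99) and Gpnmb (-5.57) were lower in line 2. In all, 1630 of 12910 genes differed by edgeR, 887 higher and 743 lower in line 2. The count was 707 without line 2 replicate 1, 600 without line 2 replicate 2 and 3506 with the replicate block, and the 10 named genes lost no call when any 1 of the 4 libraries was left out.

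Of the 6 gene groups that parted WT from line 1, all but the inflammatory genes also parted the lines. Interferon-stimulated genes were lower in line 2 than in line 1 at 17 of 28 (26 when adjusted over the list alone; median -2.90, adjusted p = 6.77e-11, adjusted p = 0.57 with an estimated correlation). Hox genes were higher at 15 and lower at 2 of 28 (18 and 4; median 2.00, adjusted p = 9.54e-10), contractile genes higher at 7 of 14 (11; 1.70, 1.19e-07), keratinocyte genes higher at 1 of 5 (4; 2.37, 0.0199) and imprinted genes higher at 6 and lower at 1 of 23 (9 and 2; 0.27, 0.0179), each with an adjusted p = 0.39 with an estimated correlation. Inflammatory genes were higher at 2 and lower at 3 of 16 (2 and 5; median -0.31, adjusted p = 0.212). P-values here measure the spread between libraries, which the protocol calls biological replicates without saying that they came from separate cultures, so part of it may be technical.

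X-linked genes did not change as a group in either line. Their median log2 fold change was 0.025 in line 1 and -0.02 in line 2, 0.021 above and -0.026 against the autosomal medians, over 414 X-linked and 12495 autosomal genes (camera adjusted p = 0.626 for each, 0.774 with an estimated correlation). In line 1, 62 X-linked genes (29 higher, 33 lower; 15%) were called against 14.3% of autosomal genes (Fisher's exact test across genes, two-sided, odds ratio 1.06, p = 0.669). In line 2 it was 19 (8 higher, 11 lower; 4.6%) against 3.5% (Fisher's exact test, odds ratio 1.31, p = 0.279). The small differences moved with single libraries. For line 1 the median of X-linked genes against autosomal genes, line 1, was -0.012 without WT replicate 1, 0.079 without WT replicate 2, 0.111 without line 1 replicate 1 and -0.059 without line 1 replicate 2. That of X-linked genes against autosomal genes, line 2, was -0.065 without WT replicate 1, 0.008 without WT replicate 2, -0.021 without line 2 replicate 1 and -0.038 without line 2 replicate 2. On simulated data a shift of 0.2 on the log2 scale over all X-linked genes passed camera at a correlation of 0.01 in both lines. Simulated genes varied independently and had no replicate effect, while the correlation estimated for X-linked genes was 0.028. A shift of this size could therefore be missed in the real data.

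Single X-linked genes did change. Apln, a vascular peptide hormone (1.75 in line 1, 1.69 in line 2), and Tspan7, a tetraspanin (0.93 and 1.33), rose in both lines. Pgk1, a glycolytic kinase (1.62), Atp7a, the copper-transporting ATPase (1.39), and Cask, a synaptic scaffold (0.99), rose in line 1, with values of 0.55, 0.29 and 0.22 in line 2 that did not pass, and each was lower in line 2 than in line 1 (adjusted p = 0.0167, 0.00386 and 0.0163). Srpx2 rose in line 2 (1.49), and stood at 0.55 in line 1 (adjusted p for the difference 0.0384). The collagen gene Col4a6 fell in both lines (-2.50 and -1.20). Shroom2 (-4.03), Mtm1 (-1.09) and Vegfd (-0.96) fell in line 1, with -0.55, -1.11 and -0.30 in line 2, none of which passed. Of the 11 X-linked genes that the naming rule took from the mean of both lines, 9 lost that call without either WT replicate, 7 without line 2 replicate 1 and 8 without line 2 replicate 2.

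Genes listed beforehand as X escape genes and genes of the X-inactivation centre stayed near WT apart from Tsix. Not all of the escape list escapes in these cells by the authors' classes. Shroom4, Mid1, Car5b, Bgn, Huwe1, Yipf6, Syap1 and Ogt are classed Monoallelic, and Kdm6a, Kdm5c, Ddx3x and 1810030O07Rik Biallelic. Of 20 measured escape genes the line 1 median was 0.11 (adjusted p = 0.169), with 1810030O07Rik (0.69) and Gemin8 (1.10) higher over all genes tested and 0 when adjusted over the list alone, where 7 had an unadjusted p under 0.05, DESeq2 called 1 and the replicate block 8. In line 2 the median was 0.03 (adjusted p = 0.763), with 0 called by edgeR or DESeq2, or adjusted over the list alone, and 2 at an unadjusted p under 0.05. Of 6 measured genes of the centre Tsix alone fell over all genes tested, in each line. Adjusted over the list alone, 3 were higher and 1 lower in line 1, with 4 called by the replicate block and 2 by DESeq2, and Ftx, a noncoding RNA gene beside Xist, had 25.9 ± 3.91 CPM in WT, 47.9 ± 16.7 in line 1 and 25.3 ± 2.96 in line 2 (adjusted p = 0.0871 and 0.986). The list medians were 0.62 (adjusted p = 0.607) and -0.22 (adjusted p = 0.132, which passed without WT replicate 1, at 0.00564, or line 2 replicate 1, at 0.0154), and in line 1 the mean, -0.55, had the opposite sign because of Tsix. Without WT replicate 1 the line 1 median of the centre was 0.13, and without line 1 replicate 2 it was 0.31. The line 1 median of escape genes was 0.02 without WT replicate 1, 0.25 without WT replicate 2 and 0.26 without line 1 replicate 1.

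Medians of several autosomes shifted. In line 1 the genes of chromosome 14 had a median log2 fold change of 0.488 (95% bootstrap interval over 422 genes 0.43 to 0.55), and 86.5% of them were positive. The medians of its replicates were 0.466 and 0.472, against -0.036 (-0.06 to -0.01) in line 2. Chromosomes 7 (-0.269 and -0.302), 8 (-0.167 and -0.138), 9 (-0.135 and -0.1) and 19 (-0.133 and -0.12) were among those lower in both lines. Chromosomes 16 (0.166 and 0.231) and 1 (0.203 and 0.096) were among those higher in both. Chromosomes 2 (0.159 and 0.01) and 13 (0.134 and -0.044) were higher in line 1, and chromosome 10 had -0.054 and 0.112. Chromosome 7 was lower along its whole length, with segment medians of -0.36 to -0.2 in line 1 and -0.35 to -0.27 in line 2. On chromosome 2 in line 1 the segments up to 54.1 Mb had medians of 0.03, -0.06 and -0.02. Those beyond it lay between 0.16 and 0.3. On chromosome 8 the shift was not even: of 10 segments in gene order, that from 105.3 to 110.2 Mb had medians of -0.51 and -0.61, and in line 2 the 7 segments before it lay between -0.1 and -0.03 and the 2 after it at -0.36 and -0.31. Genes are not replicates, and these intervals describe the spread over genes.

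**Figure D2:**
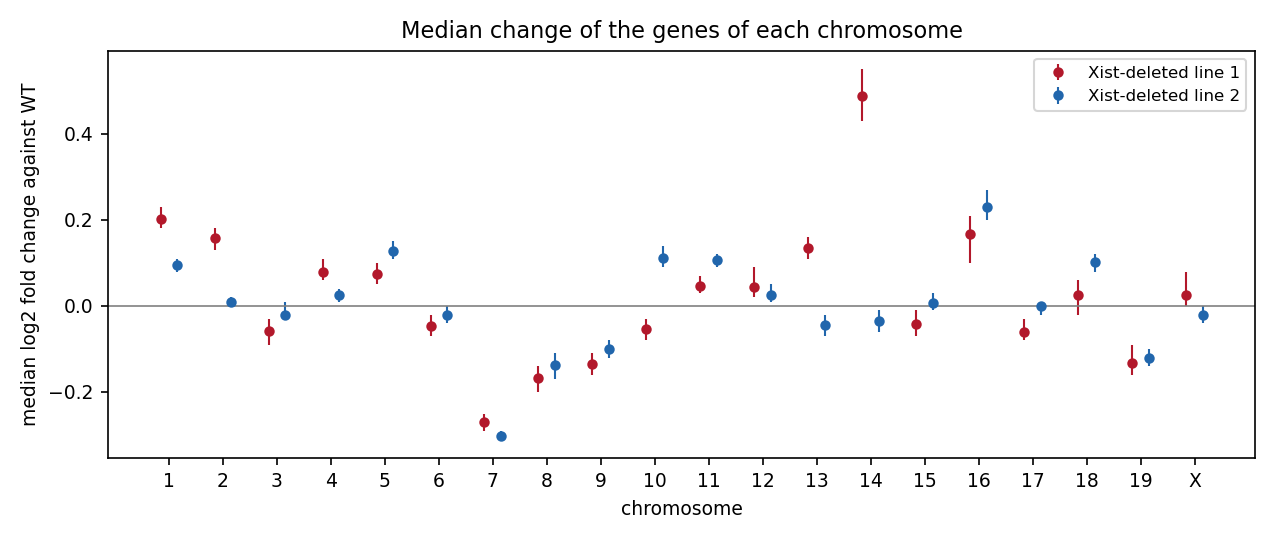
Points are the median log2 fold change against WT of the genes of each chromosome in line 1 (red) and line 2 (blue), with 95% bootstrap intervals over genes. Chromosome 14 stood at 0.488 in line 1 and -0.036 in line 2, and the X at 0.025 and -0.02.

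The authors' deposited table of allele reads covered 205 X-linked genes, 186 of them classed Monoallelic and 19 Biallelic by the authors. The mus allele gave 2.59% ± 0.33 (SD over libraries, n = 2) of reads in Monoallelic genes in WT, 2.93% ± 0.34 in line 1 and 2.62% ± 0.41 in line 2, and in Biallelic genes 41.9% ± 0.65, 45% ± 2.1 and 42.3% ± 1.1. Within replicate numbers 1 and 2, line 1 lay above WT by 0.337 and 0.358 percentage points in Monoallelic genes and by 1.97 and 4.09 in Biallelic genes, and line 2 differed by -0.0298 and 0.087 and by 0.0657 and 0.67, without a test. Single genes carried most of the Monoallelic difference in line 1 and part of the Biallelic one: without Msn and Sh3kbp1 the Monoallelic differences were 0.116 and 0.0129, and without Med14 the Biallelic ones were 0.992 and 2.19. No gene of the authors' deposited table carried the class XiRestored, a name the authors' site lists use, and all 205 genes had the same class in each of its 4 class columns. Because the authors made the classes from these libraries, they are not independent evidence of the direction. Total RNA of the classes did not move: the median log2 fold change was 0.022 in line 1 and -0.018 in line 2 for Monoallelic genes, of which 5 rose and 9 fell in line 1 and 1 rose and 2 fell in line 2. It was -0.015 and -0.011 for Biallelic genes, of which 1 rose in line 1 (camera adjusted p = 0.993 for each class and line, also with an estimated correlation). Leaving out single libraries moved these medians between -0.041 and 0.085 in line 1 and between -0.047 and 0.021 in line 2.

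Reads of the mus allele rose at 3 genes of line 1, by an edgeR test of the allele ratio that was chosen after the data were seen. For Sh3kbp1, an endocytic adaptor, the WT libraries had 4.5 and 7 mus reads beside 195.5 and 319 cas reads, and the mus share was 10.3% and 10.8% in line 1 (change of the log2 allele ratio 2.44). For Msn, the membrane linker moesin at X:96096046-96168553, it was 0.493% and 1.1% against 3.44% and 8.74% (2.93, adjusted p = 2.7e-06). For Med14, a Mediator subunit of the Biallelic class, it was 30.1% and 28.1% against 43% and 47.7% (1.07, adjusted p = 0.00416). The calls differed with the settings: Msn was lost with unrounded reads or with values ending in 0.5 rounded up, Med14 without WT replicate 1 or WT replicate 2, and Msn and Med14 without line 1 replicate 2. In line 2 edgeR called 0 genes (3 at an unadjusted p under 0.05, 0 with the replicate block, 1 with values ending in 0.5 rounded up); Mid1 had 1.25% and 2.48% in WT and 9.65% and 9.84% in line 2 (adjusted p = 0.164). Total RNA of Msn did not change (-0.07, adjusted p = 0.846).

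**Figure D3:**
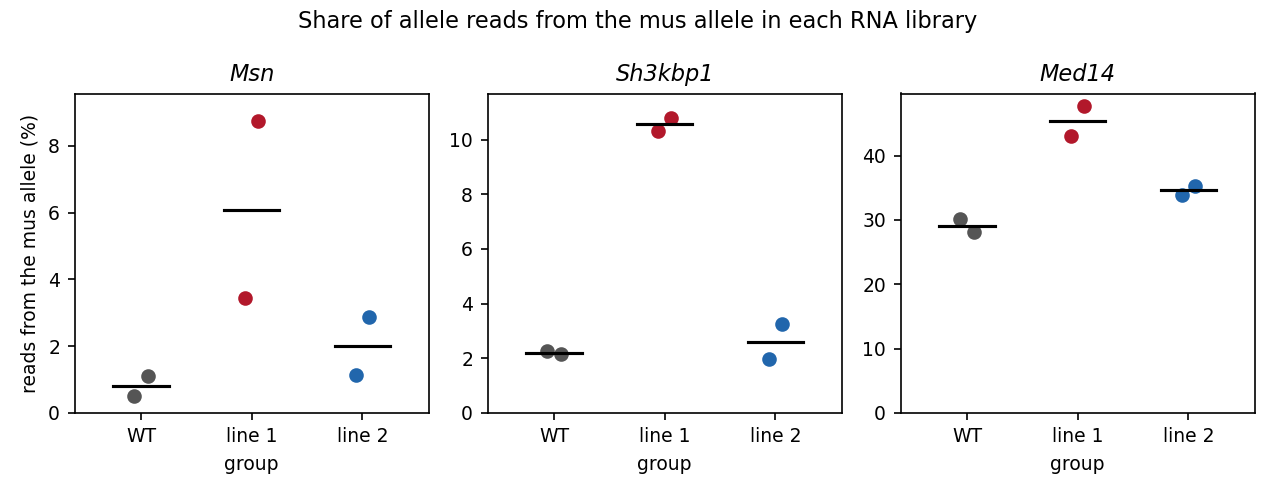
Points are the share of allele reads from the mus allele in each RNA library (vertical axis, percent, from 0), with black bars at the group means of 2 libraries. For Sh3kbp1 both line 1 libraries, at 10.3% and 10.8%, lay above those of line 2, at 1.96% and 3.25%.

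Some of the sites that the authors class as XiRestored in accessibility touched sites of the same class in BRG1 binding. The authors' deposited lists held accessibility sites (356 Monoallelic, 27 Biallelic, 37 XiRestored) and BRG1 sites (887 Monoallelic, 60 Biallelic, 189 XiRestored), all on the X. Of the 189 XiRestored BRG1 sites 25 (13.2%) overlapped an XiRestored accessibility site by at least 1 base, against 0 of the 947 other BRG1 sites (Fisher's exact test across sites, two-sided, adjusted p = 7.51e-20), and 22 of the 37 accessibility sites were involved. Of 887 Monoallelic BRG1 sites 89 (10%) overlapped a Monoallelic accessibility site, against 0 of 249 others (adjusted p = 4.56e-10), and of 60 Biallelic sites 9 (15%) overlapped a Biallelic one (odds ratio 93.6, adjusted p = 2.67e-10). Between unlike classes 2 XiRestored BRG1 sites overlapped Biallelic accessibility sites and the other pairs gave 0, where a count of 0 allows shares of up to 0.338%, 5% and 1.59% of the Monoallelic, Biallelic and XiRestored BRG1 sites. Overlaps were short, with medians of 54 bases for Monoallelic, 139 for Biallelic and 56 for XiRestored pairs, and 9, 2 and 3 sites remained when the overlap had to cover a fraction of at least 0.5 of the shorter site (adjusted p = 0.395, 0.0204 and 0.0204). The authors made both kinds of list, and sites are not replicates.

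XiRestored accessibility sites lay away from promoters. Of 37, 5 (13.5%) were within 1 kb of an annotated transcription start, against 182 of 356 Monoallelic sites (51.1%; Fisher's exact test, two-sided, odds ratio 0.15, adjusted p = 4.65e-05) and 11 of 27 Biallelic sites (40.7%; odds ratio 0.233, adjusted p = 0.0578). Of the XiRestored sites 40.5% lay in a gene body, against 65.7% of Monoallelic sites (odds ratio 0.356, adjusted p = 0.0223). For BRG1 sites the shares within 1 kb were 8.12% (Monoallelic), 8.33% (Biallelic) and 4.76% (XiRestored), which did not differ (adjusted p = 0.258 for XiRestored against Monoallelic). The share of XiRestored sites among BRG1 sites was listed per 20 Mb of the X, without a test: they were 45.4% of the BRG1 sites between 60 and 80 Mb, 32% between 80 and 100 Mb, 22.5% between 100 and 120 Mb and 21% in the first 20 Mb, and 2.41% to 9.74% elsewhere.

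**Figure D4:**
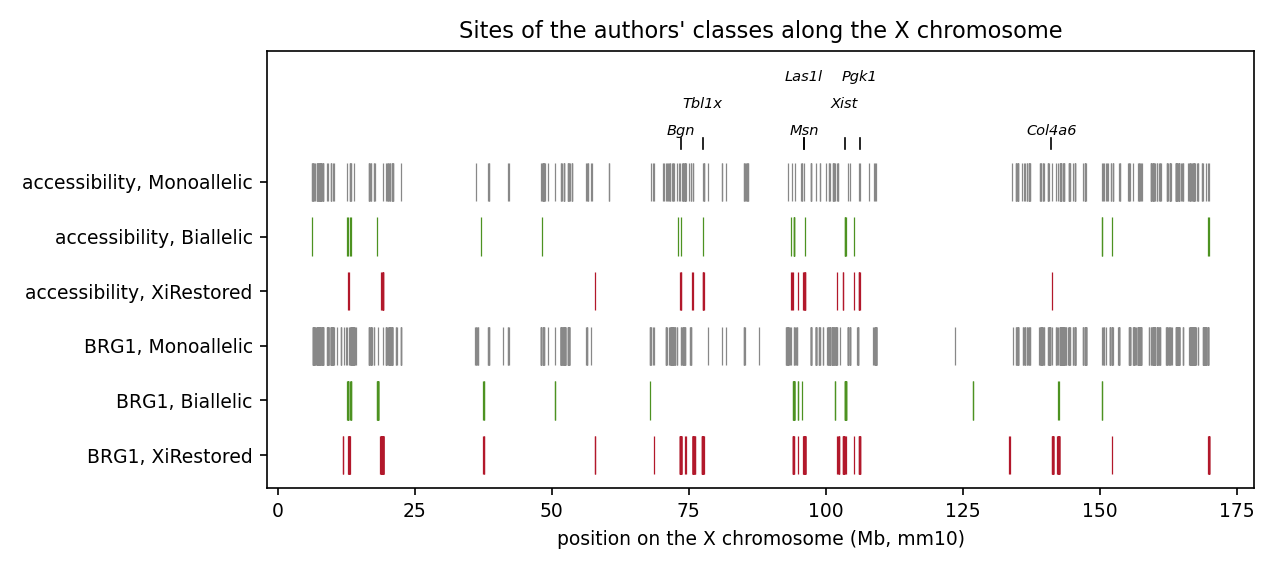
Each tick is a site of the authors' accessibility or BRG1 classes at its position on the X (Mb, mm10), 1 lane per class, with gene positions on top. Most of the 37 XiRestored accessibility sites fall in the first 20 Mb or between 60 and 120 Mb.

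RNA of genes beside restored sites was compared with that of other X-linked genes. The 9 tested genes with a start within 10 kb of an XiRestored accessibility site were Haus7, Bgn, Vbp1, Pls3, Las1l, 5530601H04Rik, Pbdc1, Atp7a and Pgk1. In line 1 their median log2 fold change was 0.518 against 0.016 in other X-linked genes (camera adjusted p = 0.0205, adjusted p = 0.284 with an estimated correlation). Pgk1 and Atp7a were the 2 called higher by edgeR, against 6 with the replicate block (camera adjusted p = 0.0218, adjusted p = 0.721 with an estimated correlation). At 50 kb the difference was 0.117 (adjusted p = 0.11). In line 2 the medians were 0.289 and -0.023 (adjusted p = 0.0936) with 0 called by edgeR and 1 higher with the replicate block. For the 20 genes near XiRestored BRG1 sites the medians were 0.203 against 0.017 in line 1 (adjusted p = 0.0523, 3 called) and 0.056 in line 2 (adjusted p = 0.241, 0 called), and at 1 kb, with 6 genes, the difference in line 1 was 0.527 (adjusted p = 0.0291, adjusted p = 0.391 with an estimated correlation). With the replicate block 9 of the 20 genes near XiRestored BRG1 sites rose and 2 fell in line 1, and 1 rose in line 2. Near Monoallelic and Biallelic sites the differences in line 1 were 0.055 and 0.124 for accessibility and -0.001 and 0.126 for BRG1 (adjusted p = 0.314, 0.314, 0.696 and 0.314).

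Sites in both XiRestored classes began, in chromosome order, at X:13022910-13023281, nearest to 5730405O15Rik, followed by X:18873999-18874326 and X:19054067-19054257, nearest to Mir221, and X:19157502-19157836, X:19157893-19158156 and X:19168315-19168489, nearest to Mir222, a microRNA. None of these genes reached the count filter of the RNA data. Among sites chosen after their values were seen, X:106186546-106187180 covered the start of Pgk1, X:106043899-106044450 lay in Atp7a, and 4 sites between X:96077821 and X:96133531 lay in or beside Msn.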

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

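All tests of causes in this part were chosen after the results were seen, with their thresholds.

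Genes of chromosome 14 were higher in line 1 along the whole chromosome. The lowest median log2 fold change of 10 segments in gene order was 0.38, as a gain of the whole chromosome would give. The median lay 0.495 above that of the other autosomes, so the scaling of the libraries does not account for it. In line 2, which also lacks Xist, the median was -0.036, so loss of Xist alone does not either. An extra copy of chromosome 14 in part or all of line 1 may be the source, a hypothesis that DNA copy number was not used here to test.

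Interferon-stimulated genes were higher in line 1 than in line 2, with a median of -2.90 for line 2 minus line 1. Of 28 genes, 17 were lower in line 2 than in line 1, so loss of Xist alone does not account for the level in line 1. Leukocytes in the cultures stay open: the summed CPM of the 19 macrophage and leukocyte genes in the table was 33.8 and 30.2 in line 1 against 24.6 and 22.9 in WT, with Cd14 called higher, while 7 of them, picked after the data were seen and without Cd14, summed to 2.97 and 1.5 against 4.55 and 4.08. In line 2 the 19 genes summed to 29.8 and 31.8 and the 7 to 2.42 and 0.846. The sum of the 19 was thus near that of line 1, although interferon-stimulated genes were lower in line 2. In the list median of interferon-stimulated genes the lower line 1 library lay 2.88 log2 units above the higher WT library, so it was not 1 library standing apart. Differences in culture were not tested, so the source of the response was left open.

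The mus share of single X-linked genes rose in line 1, and genes near restored accessibility sites gained more. A shift of allele assignment in the whole library stays open: without the called genes the pooled mus share of line 1 changed by 0.116 and 0.0129 percentage points in Monoallelic genes and by 0.992 and 2.19 in Biallelic genes, within replicate numbers 1 and 2. Distance was taken here from the whole gene body, unlike the RNA test near sites, which used transcription starts. The 7 Monoallelic genes within 10 kb of an XiRestored accessibility site were Haus7, Bgn, Tbl1x, Pdk3, Las1l, Msn and Col4a6. They gained 3.02 points on average, 3.07 more than 179 others, and 7 of 7 gained (permutation of genes, adjusted p = 0.00048). The difference was 2.69 without Msn, 1.65 at 50 kb and 1.21 at 100 kb. In line 2 the difference was 1.04 (permutation, adjusted p = 0.0733), and near XiRestored BRG1 sites within 10 kb it was 1.60 in line 1 and 1.26 in line 2 (permutation, adjusted p = 0.00108 and 0.00464). Near these BRG1 sites 11 of 14 genes gained in line 1 and 8 of 14 in line 2. The 14 include Mid1, at 1.25% and 2.48% in WT and 9.65% and 9.84% in line 2. The line 2 difference was not tested without Mid1. The lowest mus value, which stands for 0, counts as reads in these shares. Of 186 Monoallelic genes, 109 and 81 had it in the WT libraries and 112 and 75 in those of line 1. At this value a share rises when cas reads fall. Total RNA of Col4a6, among the 7 genes near accessibility sites, fell from 225 to 40.1 CPM in line 1. Its gain therefore need not be mus expression. The gains were not tested without genes at this value. Partial reactivation at restored sites may be a candidate explanation, a hypothesis that leaves out Sh3kbp1, with no such accessibility site within 100 kb; genes are not replicates, and the labels tie the authors' site lists to line 1 among other samples.

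Between the lines 1630 genes differed. Contractile genes had a median of 1.70 for line 2 minus line 1. Keratinocyte genes had a median of 2.37. Hox genes had a median of 2.00. Imprinted genes had a median of 0.27. The change of the log2 allele ratio between lines was -1.69 for Msn, a call that was lost with unrounded reads, with values ending in 0.5 rounded up, without line 1 replicate 2 and without line 2 replicate 1. It was -2.09 for Sh3kbp1, whose call held in each of these.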

How the results depend on the processing

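Tests of genes shared by both lines, allele tests and leave-one-out tests of lists were chosen after the results were seen, as were unrounded, thinned and densest-gene alternatives; the others in this part were planned. With 2 libraries per group, counts of genes moved most. With the replicate block they were 4182 (line 1), 1568 (line 2), 2878 (mean) and 3506 (between), and 344 higher and 510 lower in both lines. Without a filter they were 948 in line 2 and 1696 in the mean, and 192 higher and 278 lower in both; with the stricter filter 79 were lower in both. With the 2 compared groups alone line 1 had 1257 and line 2 had 790, against 1846 and 462 in the shared fit. Leaving out 1 library gave 718 to 2361 in line 1, 23 to 52 in line 2, 267 to 1558 in the mean and 600 to 1991 between lines. It gave 4 to 148 higher and 5 to 238 lower in both. The cause was not tested.

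Leaving out 1 library moved the median of X-linked genes against autosomal genes, line 1, from -0.059 to 0.111 and that of X-linked genes against autosomal genes, line 2, from -0.065 to 0.008. Medians of Monoallelic genes moved from -0.041 to 0.085 and from -0.047 to 0.021, and of Biallelic genes from -0.014 to 0.065 and from -0.033 to 0.016. With an estimated correlation 0 of 6 lists passed in line 1 and 0 of 3 in line 2, where leaving out 1 library gave 3 to 5. With an overlap of 0.5 of the shorter site 9 Monoallelic pairs remained (Fisher's exact test, adjusted p = 0.395). RNA near restored accessibility sites differed by 0.117 at 50 kb, and near restored BRG1 sites by 0.527 at 1 kb. Restored against Biallelic accessibility sites had an odds ratio of 0.201 at 5 kb (Fisher's exact test, adjusted p = 0.0277). Allele calls were 1 in line 2 with values ending in 0.5 rounded up, and between lines 1 with unrounded reads, 1 with values ending in 0.5 rounded up and 4 with the block. Leaving out 1 library gave 1 to 3 calls in line 1 and 1 to 3 between lines, and in line 2 edgeR called 0. Depth limits calls in genes with few reads, and most allele changes of 4-fold would be missed.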

Other observations

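Genes of the Dlk1 and Meg3 imprinted region parted between the lines. Meg3 and Rian were nearly lost in both lines, while Dlk1 fell by 4.53 in line 1 and stood at 0.14 in line 2 (adjusted p = 0.826), a difference of 4.67 between the lines (adjusted p = 0.000287). Peg3 was nearly absent in line 1 and not in line 2. These genes were picked after their values were seen.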
